A study of Homo sapiens with 9 samples.

How the data were processed

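RNA of 9 samples of OVISE cells, 3 with DMSO, 3 with doxycycline-induced ARID1A and 3 with GSK126, was hybridised to an Illumina expression array of 47323 probes. Groups, replicate numbers and batches were taken from the sample labels. The deposited non-normalised table holds a linear intensity per probe and array, exported from GenomeStudio per the submitters' processing notes (version not given in the sources used here), with no background subtracted as far as its values show. Beside each intensity the deposited table gives a detection p-value, made by the authors' software against negative controls that are not in the table used here. A second deposited table, the authors' value table, holds intensity values on a linear scale. All its columns share 1 set of quantiles, each column keeps the order of its array's raw values (rank correlation 1), and the column medians are 329.794, or 329.797 on 1 array. It was therefore read as quantile normalised without background subtraction or centring. The mean raw quantiles of the 9 arrays differ from its quantiles by −0.0369% to 3.58% (median 0.88%), so which arrays set its quantiles is unknown. The array's genome build is not given in the sources used here, and no coordinates are printed.

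Raw intensities were processed with limma 3.58.1 in R 4.3.3. The neqc function corrected the background by normexp, with the negative controls inferred from the detection p-values, added an offset of 16, quantile normalised the arrays and took log2. Probes with a detection p below 0.05 on at least 3 of the 9 arrays were kept, which left 23014 probes (48.63%). The platform annotation listed 30113 probes with 1 gene symbol, 8 with several and no gene for 17202; symbols of 30074 probes were updated through the Entrez identifier with RefSeq names of assembly GRCh38.p14, and 39 kept the annotation's own. Probes without exactly 1 symbol (5947 of those kept) were tested only as probes. Each of 12698 genes was represented by its kept probe with the highest mean over the 9 arrays, and 3476 genes had more than 1 kept probe. Of 103 other probes of the genes called after ARID1A restoration, 91 had the sign of the representing probe and 0 were called with the opposite sign. A further 28 genes were called for ARID1A against DMSO only through another probe, and 21 for GSK126 against ARID1A. The gene counts below leave these out.

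All 9 arrays entered 1 linear model with 3 group means, fitted with lmFit and eBayes (6 residual degrees of freedom), and the 3 pairwise comparisons were tested two-sided with Benjamini-Hochberg adjustment over 12698 genes at 0.05. Every adjusted p of a gene comes from this limma model unless a sentence names another. A gene named below that was not detected on every array of its dimmer group has only a bound there, given as at least N-fold. Such a bound compares means and makes no allowance for the spread between arrays. The adjusted p of such a gene tests its fitted difference, not the bound. The labels give every group the batches 1 to 3, so replicate numbers mark a shared batch and pair the samples. Deviations from group means correlated between 0.102 and 0.326 for the 9 pairs of arrays from the same batch and between −0.227 and 0.042 for the 18 pairs from different batches. A second model with batch as a block (4 residual degrees of freedom) is printed beside a list, a gene named by the rule below or a count of genes over all genes tested where it changes the call or moves the count by more than 1.5 times.

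Genes were named by a rule. For ARID1A or GSK126 against DMSO it took the 10 largest rises and 10 largest falls among called genes with 1 sign in all 3 batches, with gaps filled from the model with the block. For GSK126 against ARID1A it took the 5 largest each way. The genes ARID1A, EZH2, EZH1, PIK3IP1, HDAC6, CDKN1A and CDKN1C were always taken. Each gene list gave up to 4 called members, at most 2 in each direction, or, if none passed, the 2 with the smallest p. No gene was called for GSK126 in either model, so that comparison names list members and the always-named genes. The groups, comparisons, models, lists, naming rule and most alternatives were fixed before the data were examined; 4 alternatives that combine the block with another choice were added after.

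There were 30 gene lists, of which 27 had at least 5 members tested: the PRC2 complex, SWI/SNF subunits, developmental Polycomb targets, PI3K-AKT inhibitors and FOXO targets, G2/M, DNA replication, p53 targets, apoptosis regulators, cholesterol synthesis, fatty acid synthesis, the unfolded protein response, the ATF4 response, oxidative phosphorylation, ribosomal proteins, interferon-stimulated genes, MHC antigen presentation, cytokines and NF-kappaB targets, epithelial junctions, mesenchymal genes, basement membrane, clear cell carcinoma markers, hypoxia and glycolysis, lysosome, NRF2 genes, core histone genes, immediate early genes and leukocyte markers. Of the others, transcripts of mitochondrial DNA had 0 members tested, fibroblast markers 1 (FBLN1) and endothelial markers 1 (VWF). Lists were tested two-sided with limma's camera at a preset correlation of 0.01, adjusted within a comparison. With the correlation estimated from the data, 0 lists passed in any comparison, and the smallest adjusted p was 0.258, 0.435 and 0.271 for ARID1A against DMSO, GSK126 against DMSO and GSK126 against ARID1A. The fry test, which asks whether the members move one way on balance, passed 8, 0 and 9 lists.

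The code was tested on simulated data for 12698 genes with the measured gene means, the spread moderated by eBayes and 200 changed genes, over 20 draws. For ARID1A against DMSO it recovered 54.9% of 1.5-fold, 93% of 2-fold and 99.8% of 3-fold changes, with 5.72% of calls wrong, and for GSK126 against DMSO 56.4%, 91.1% and 99.3%, with 5.18% wrong. The simulated arrays carry no batch effect, so they do not describe the model with the block. The moderated spread varies less between genes than the measured one, so recovery in the measured data may differ. Unchanged groups against shared controls were simulated in 100 draws. That simulation was first run with noise made as mixtures of the measured residuals and then, after its result was seen, with noise independent between genes. Both are given, because mixtures of residuals can make the noise of different arrays alike. Their correlation was computed for mixtures of the residuals of the model with the block, which served the covariances between batches described below. It ran from −0.983 to 0.875, far beyond the measured correlations.

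Alternatives were the block, no background correction, the authors' value table, median centring, no filter or a stricter one (detection p below 0.01 on all 9 arrays), a mean-variance trend, array weights, fits of only the 2 groups compared, other rules for several probes, other thresholds, and leaving out arrays or batches. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.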

Results

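Gene expression was measured in OVISE cells, an established line of clear cell ovarian carcinoma that carries mutated ARID1A, a DNA-binding subunit of the SWI/SNF chromatin remodelling complex. The cells were grown in 3 dimensions in Matrigel, a basement membrane extract, and received the vehicle DMSO, 1 µg/mL doxycycline to switch on wild-type ARID1A, or 5 µM GSK126, an inhibitor of the histone H3 lysine 27 methyltransferase EZH2. Each of the 3 groups had 3 arrays, and replicates 1, 2 and 3 of every group came from labelled batches 1, 2 and 3. Of 47323 probes, between 21317 and 22517 per array had a detection p below 0.05, and the median raw intensity lay between 316.645 and 348.539. Expression values below are normalised log2 intensities, and differences are log2 fold changes with their standard error (SE) from 3 arrays against 3. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

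The targeted gene was examined first. ARID1A had 2 probes above background, and they differed. On probe ILMN_1734496 the signal was not above background on any DMSO or GSK126 array and was detected on 3 of 3 arrays of cells with induced ARID1A, at 8.67 ± 0.38 (SD, n = 3). The measured mean in DMSO was 5.68 ± 0.21, so that the induced level was at least 3.74-fold higher (limma adjusted p = 0.000319 over all probes). Bounds of this kind set the brighter group's mean against the dimmer group, with each array not above background raised at least to the dimmest signal above background on that array. The brighter probe, ILMN_1797341, which represents the gene in the tests, read 11.07 ± 0.06 in DMSO, 10.94 ± 0.10 with induced ARID1A and 10.86 ± 0.03 with GSK126. Its difference of −0.13 (SE 0.08) between induced cells and DMSO did not pass the test (limma adjusted p = 0.442). EZH2 transcript was at 10.37 in DMSO, with a difference of −0.17 (SE 0.15, limma adjusted p = 0.569) after ARID1A induction and −0.28 (SE 0.15, limma adjusted p = 0.607) under GSK126. Its paralogue EZH1 was above background on 2 of 3 arrays with induced ARID1A and did not pass there (limma adjusted p = 0.704), and under GSK126 it differed from DMSO by 0.12 (limma adjusted p = 0.914).

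**Figure D1:**
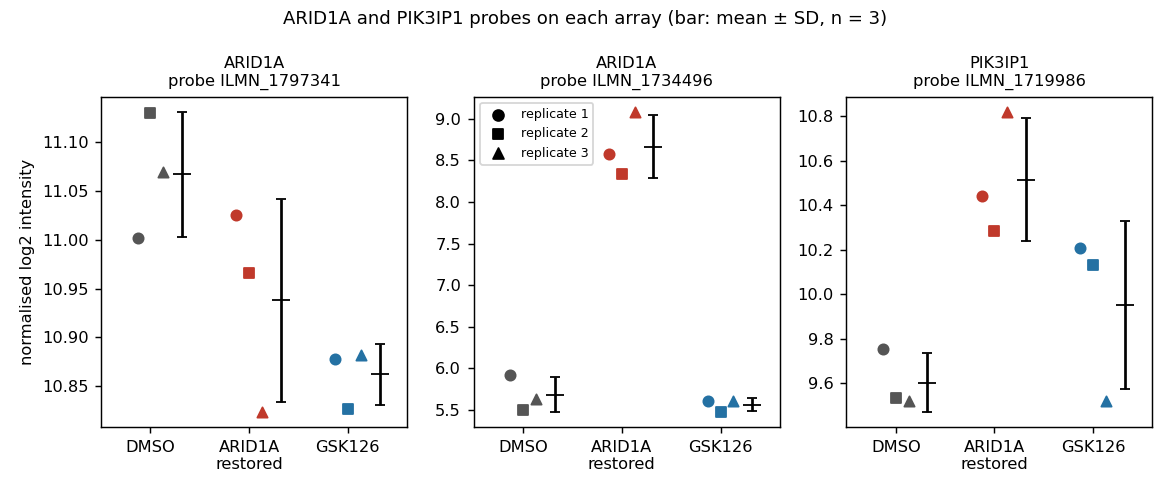
Normalised log2 intensity (vertical axes, a scale of its own per panel) of both ARID1A probes and the PIK3IP1 probe on each of the 9 arrays, by group; marker shapes are replicates, and bars are the mean ± SD of 3 arrays. On ILMN_1734496 the 3 arrays with induced ARID1A lie between 8.34 and 9.09, while no other array exceeds 5.92.

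The comparison of induced ARID1A with DMSO asks which genes respond to restoring the wild-type subunit in mutant cells. GALNT16, a glycosyltransferase that starts mucin-type O-glycans, was at least 10.8-fold higher than in DMSO. The carbonic anhydrase CA12 was at least 6.81-fold higher, the actin-bundling protein ESPN at least 5.75-fold, the keratin KRT13 at least 4.61-fold and DENND2A at least 4.32-fold, each against a DMSO level not above background. The myosin light chain MYL4 (at least 8.75-fold), the urothelial plaque protein UPK2 (at least 5.19-fold), the sodium channel subunit SCNN1G (at least 4.79-fold) and the secreted glycoprotein OLFM4 (at least 4.70-fold) rose from levels above background on 1 of 3 DMSO arrays. The diamine oxidase AOC1, detected on 3 of 3 arrays of both groups, rose by 2.65 (SE 0.36). The TNF family ligand LTB and the lymphocyte activation antigen CD69, each above background on 1 of 3 arrays with induced ARID1A, were at least 5.20-fold and 5.18-fold higher in DMSO. Their other probes were not above background on any array with induced ARID1A, and of these that of CD69 passed over all probes (limma adjusted p = 0.0116) and that of LTB did not (0.0819). Among genes detected on 3 of 3 arrays of both groups that fell were the chemokines CCL20 at −2.35 (SE 0.40) and CXCL1 at −1.98 (SE 0.24), and complement factor CFB at −2.08 (SE 0.40). The acute-phase protein SAA2 (−1.70, SE 0.34), the prostaglandin synthase PTGS2 (−1.59, SE 0.20) and the adhesion molecule CEACAM6 (−1.51, SE 0.22) fell as well. TNF was not above background with induced ARID1A and was at least 1.87-fold higher in DMSO. FEZ1 fell by 2.23 (SE 0.37) on its brightest probe, while its other 2 probes did not pass over all probes (limma adjusted p = 0.328 and 0.738). Limma adjusted p for these 20 genes ran from 1.93e-05 for ESPN to 0.0396 for OLFM4.

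In all, 361 of 12698 genes changed, 255 upward and 106 downward, and 109 changed at least 2-fold. Each of the 361 moved the same way in all 3 batches, which the call itself nearly ensures, so this adds no separate support. With batch as a block, 774 genes passed (485 higher and 289 lower), 354 of them among the 361. Without any 1 of the 6 arrays compared the count was between 92 (without DMSO replicate 1, or without replicate 3 of the induced cells) and 218 (without replicate 2 of the induced cells), and the group that induced ARID1A is also the only one that received doxycycline.

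**Figure D2:**
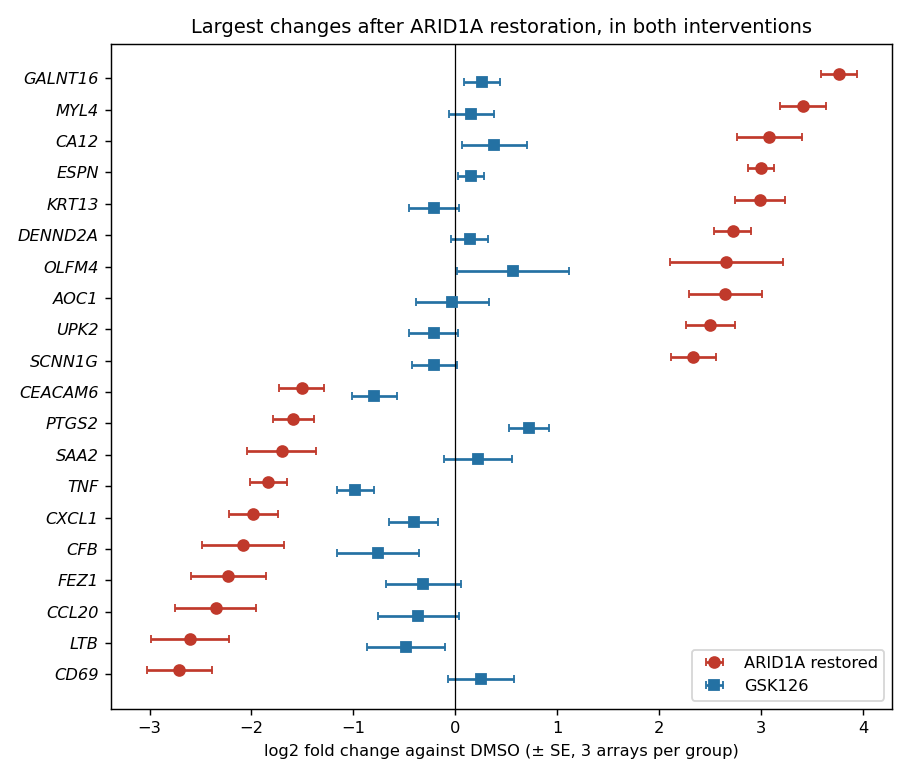
Log2 fold change against DMSO (horizontal axis, ± SE, 3 arrays per group) of the 10 largest rises and 10 largest falls after ARID1A restoration, shown for both interventions as fitted values, also where a level was not above background. GALNT16 stands at 3.77 with induced ARID1A, measured from a DMSO level not above background, and at 0.26 under GSK126, and PTGS2 at −1.59 and 0.72.

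Of the gene lists, cytokines and NF-kappaB targets moved furthest down after ARID1A restoration, with a median of −0.42 over 20 members. Of these members 1 rose and 5 fell over all genes tested, and 1 rose and 10 fell adjusted over the list alone (camera adjusted p = 3.92e-07, and adjusted p = 0.258 with an estimated correlation). CCL20 and CXCL1 were among those that fell, and IL1B, an inflammatory cytokine, went the other way, at least 2.71-fold higher than a DMSO level not above background. The list called core histone genes, which as written also holds the linker histone genes HIST1H1C and H1F0, had a median of 0.78. Of its 16 members 13 were positive and 3 negative. Over all genes 4 rose (10 with batch as a block), and 12 rose adjusted over the list alone (camera adjusted p = 2.82e-06, and adjusted p = 0.398 with an estimated correlation). H4C8 rose by 1.54 (SE 0.28) and H2AC18 by 1.27 (SE 0.20), and the other probe of H2AC18 stood at 0.76 (limma adjusted p = 0.216 over all probes). Lysosome and autophagy genes rose with a median of 0.19 over 27 members, 2 passing over all genes (5 with the block) and 8 adjusted over the list alone (camera adjusted p = 3.46e-06, and adjusted p = 0.258 with an estimated correlation). The lysosomal protease CTSD rose by 0.51 (SE 0.08) and the autophagy protein WIPI1 by 0.41 (SE 0.09). For WIPI1 the limma adjusted p was 0.0481, and 0.0777 over all probes. The call of WIPI1 was lost in 14 of 15 settings that leave out an array or batch.

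Epithelial junctions and keratins had a median of 0.18 over 27 members, 18 positive and 9 negative. Of these members 3 rose over all genes and 9 adjusted over the list alone (camera adjusted p = 0.00385, and adjusted p = 0.258 with an estimated correlation). KRT80 rose by 0.88 (SE 0.14) and KRT8, a keratin of simple epithelia, by 0.46 (SE 0.09). Basement membrane and integrin genes had a median of 0.15 over 24 members, 16 positive and 8 negative. Over all genes 1 rose (5 with batch as a block), and 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.036, and adjusted p = 0.605 with an estimated correlation). The laminin chain LAMB2 rose by 0.86 (SE 0.13). Inhibitors of PI3K-AKT signalling and FOXO targets had a median of 0.10 over 30 members, 18 positive and 12 negative. Of these members 5 rose over all genes (8 with the block) and 8 adjusted over the list alone, where the block adds 3 that fell (camera adjusted p = 0.0244, and adjusted p = 0.308 with an estimated correlation). The transcriptional repressor BCL6 rose by 1.00 (SE 0.13). PIK3IP1, an inhibitor of PI3K that the study itself picked using these samples and which is therefore not independent evidence for the list, rose by 0.91 (SE 0.20), from 9.60 to 10.52 (limma adjusted p = 0.0449). Without 1 array, the basement membrane list lost its call without DMSO replicate 1 (adjusted p = 0.158) or replicate 2 of the induced cells (0.128), as did the PI3K-AKT and FOXO list without DMSO replicate 3 (0.0776) or replicate 2 of the induced cells (0.117). The median of the latter list was 0.03 without replicate 2 of the induced cells, 0.16 without their replicate 3 and 0.19 without DMSO replicate 2. Over all probes in place of genes, the adjusted p of PIK3IP1 was 0.0661, and without any 1 of the 6 arrays compared it was between 0.0591 (without replicate 2 of the induced cells) and 0.148 (without replicate 3 of the induced cells).

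Cell cycle lists shifted down by small amounts, and these shifts rested in part on single arrays. G2/M and mitosis genes had a median of −0.20 over 36 members, 33 of them negative, and 1 of them, the cytokinesis factor ECT2, fell by 0.60 (SE 0.09) over all genes and adjusted over the list alone (camera adjusted p = 0.00315, and adjusted p = 0.734 with an estimated correlation). DNA replication and G1/S genes had a median of −0.15, and all 34 members were negative with 0 passing by limma over all genes or adjusted over the list alone (camera adjusted p = 0.000746, and adjusted p = 0.626 with an estimated correlation). Without replicate 3 of the induced cells the G2/M median was 0.01 (adjusted p = 0.67) and the DNA replication median −0.05 (0.22). Without DMSO replicate 2 the G2/M median was −0.10 (adjusted p = 0.0997). Immediate early genes had a median of −0.25 over 21 members, of which 1 fell over all genes (4 with batch as a block). Adjusted over the list alone 1 rose and 6 fell (2 and 9 with the block). The list had a camera adjusted p of 0.00687, and 0.258 with an estimated correlation. FOS fell by 0.73 (SE 0.16, limma adjusted p = 0.0468, and 0.0697 over all probes). Its call was lost in 14 of 15 settings that leave out an array or batch. The lists of interferon-stimulated genes (median −0.26, 35 members, camera adjusted p = 0.018), MHC antigen presentation (median −0.12, 19 members, camera adjusted p = 0.0367) and the ATF4 stress response (median −0.14, 24 members, camera adjusted p = 0.014) also had medians below 0, with 0.03 for the interferon list and 0.00 for the MHC list in batch 3. With an estimated correlation their adjusted p was 0.734, 0.626 and 0.258. The interferon and MHC lists lost their calls without DMSO replicate 1 (adjusted p = 0.0635 and 0.141), DMSO replicate 3 (0.123 and 0.108) or replicate 2 of the induced cells (0.812 and 0.471). Without the last of these arrays their medians were −0.06 and −0.04. The interferon median was −0.17 without DMSO replicate 3, and the MHC median was −0.07 without DMSO replicate 1 and −0.19 without DMSO replicate 2. Each of the 3 lists had 0 members past limma's threshold over all genes or adjusted over the list alone. With batch as a block 2 interferon-stimulated, 1 MHC and 2 ATF4 genes fell over all genes. Adjusted over the list alone with the block, 2, 5 and 3 fell and 1 MHC gene rose. CD74, the invariant chain of MHC class II, differed by −1.07 (limma adjusted p = 0.118, and 0.0212 with batch as a block), IRF1 by −0.39 (0.126, and 0.0487 with the block) and PCK2 by −0.46 (0.0902, and 0.0272 with the block).

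The other lists did not pass camera after ARID1A restoration, although single members did. The SWI/SNF ATPase SMARCA2 rose by 0.39 (SE 0.08) in a list of 20 other subunits (median −0.08, camera adjusted p = 0.584). Its limma adjusted p was 0.0392, and 0.0645 over all probes. The call of SMARCA2 was lost in 14 of 15 settings that leave out an array or batch. Among 40 developmental regulators known as Polycomb targets (median −0.09, camera adjusted p = 0.574), MEIS2 rose by 0.74 (SE 0.13) and FOXA2 fell by 0.62 (SE 0.11), where 3 fell with batch as a block. The pro-apoptotic BMF rose by 1.11 (SE 0.18) and PMAIP1 fell by 0.62 (SE 0.10) among 31 apoptosis regulators (median −0.01, camera adjusted p = 0.473), of which 2 fell with the block. The elongase ELOVL6 rose by 1.71 (SE 0.09) in the fatty acid synthesis list, whose 10 members had a median of −0.16 and a mean of 0.02 (camera adjusted p = 0.349). SERPINA1 rose by 1.90 (SE 0.24) and GPX3 by 0.96 (SE 0.16) among 18 clear cell carcinoma markers (median 0.01, camera adjusted p = 0.574). TNC rose by 0.72 (SE 0.09), and by 2.51 (SE 0.22, limma adjusted p = 0.00166 over all probes) on its other probe, among 16 mesenchymal genes (median 0.05, mean −0.04, camera adjusted p = 0.923, with 3 falling under the block). AKR1B10, above background on 2 of 3 DMSO arrays, was at least 2.26-fold higher among 16 NRF2 and metallothionein genes (median 0.09, camera adjusted p = 0.574). Of 29 hypoxia and glycolysis genes, 1, CA12, rose over all genes, 2 with the block and 4 adjusted over the list alone (median −0.01, mean 0.09, camera adjusted p = 0.713).

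No member passed over all genes for the PRC2 complex (11 members, median −0.12, camera adjusted p = 0.428), p53 targets (24 members, median 0.02, 0.754), cholesterol synthesis (19 members, median −0.02, 0.702), the unfolded protein response (18 members, median −0.05, mean 0.02, 0.845), oxidative phosphorylation (32 members, median 0.03, mean −0.01, 0.902) or ribosomal proteins (35 members, median −0.01, 0.474). The cell cycle inhibitor CDKN1A differed by 0.50 (SE 0.17, limma adjusted p = 0.15, and 0.0221 with batch as a block), the p53 target PHLDA3 by 0.33 (0.237, and 0.0436 with the block), the deacetylase HDAC6 by 0.27 (0.182) and CDKN1C by −0.19 (0.676). For cells other than carcinoma cells, 6 leukocyte markers had a median of 0.11 (camera adjusted p = 0.713), and the fibroblast marker FBLN1 differed by −0.00 (limma adjusted p = 0.995). VWF, an endothelial marker, was at least 1.43-fold higher with induced ARID1A than in DMSO, where it was not above background (limma adjusted p = 0.000169).

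**Figure D3:**
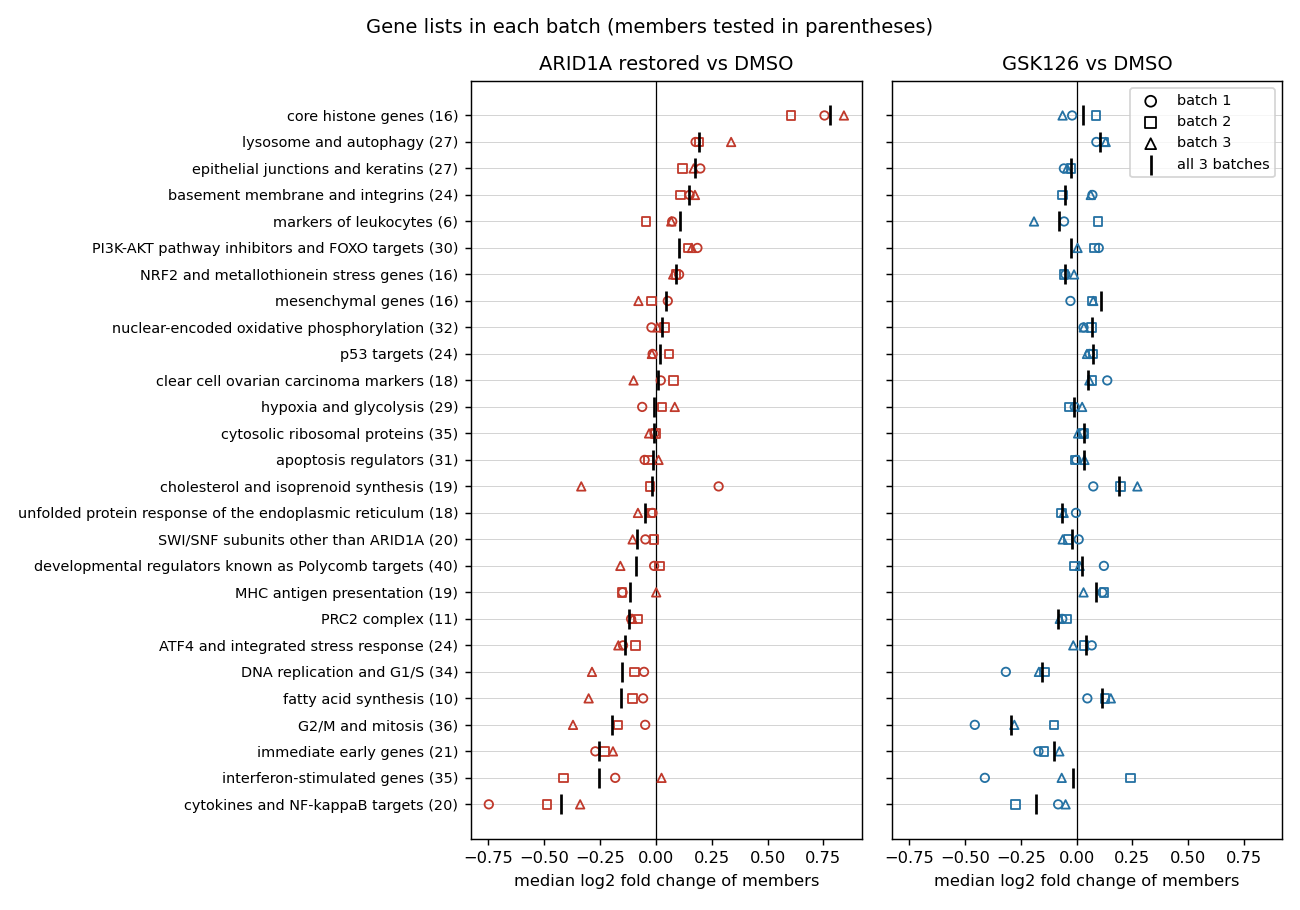
Median log2 fold change against DMSO (horizontal axes) of each tested gene list in each labelled batch (open markers) and over the 3 batches (black ticks), for both interventions, with the number of members tested in parentheses. Core histone genes stand at 0.78 with induced ARID1A and at 0.03 under GSK126, and interferon-stimulated genes lie between −0.41 and 0.24 over the batches under GSK126.

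The comparison of GSK126 with DMSO asks what inhibition of EZH2 changes in the same cells. No single gene passed the test, and the shifts were small. G2/M and mitosis genes shifted down with a median of −0.29 over 36 members, 35 of them negative, and DNA replication genes with a median of −0.16 over 34. Neither shift passed with an estimated correlation (adjusted p = 0.658 and 0.56). Values of members included −0.49 (SE 0.09) for ECT2, −0.41 (SE 0.13) for the topoisomerase TOP2A, −0.52 (SE 0.14) for CDC45 and −0.54 (SE 0.16) for MCM10, both of the replication machinery. Lysosome and autophagy genes shifted up with a median of 0.10 over 27 members, with 0.81 (SE 0.21) for the glycoprotein GPNMB (adjusted p = 0.56 for the list with an estimated correlation). The death ligand TNFSF10 stood at 0.96 (SE 0.21), from 10.50 to 11.46 (limma adjusted p = 0.253), and TNF, above background on 2 of 3 GSK126 arrays, was at least 1.77-fold higher in DMSO, which did not pass (limma adjusted p = 0.2).

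By limma 0 of 12698 genes passed, the smallest adjusted p was 0.145, and 1185 genes had an unadjusted p below 0.05, where 634.9 are expected by chance; with batch as a block 0 passed and 1741 had an unadjusted p below 0.05. With batch as a block and values chosen after seeing the data, 65 genes passed on the authors' normalised table, 69 on intensities without background correction and 129 with a mean-variance trend. The lists passed camera at an adjusted p of 2.13e-07 for G2/M, 4.71e-06 for DNA replication, 0.000763 for lysosome, 0.0449 for immediate early genes (median −0.10, with JUNB at −0.42), 0.0477 for fatty acid synthesis (median 0.11, with SCD at 0.40) and 0.0477 for cholesterol synthesis (median 0.19, with DHCR7 at 0.34 and HSD17B7, which goes the other way, at −0.30). The adjusted p of these 6 lists with an estimated correlation was 0.658, 0.56, 0.56, 0.435, 0.435 and 0.658. With batch as a block, fatty acid and cholesterol synthesis each had an adjusted p of 0.0759. Adjusted over the list alone, 1 G2/M member fell (3 with the block) and 2 fatty acid members rose. No lysosome member rose (4 with the block), and no member of the other 3 lists passed. Of the 9 settings without 1 array, the cholesterol list lost its call in 7 (adjusted p up to 0.507, without GSK126 replicate 3), the fatty acid list in 6 (up to 0.142, without DMSO replicate 2) and the immediate early list in 5 (up to 0.154, without DMSO replicate 2). Without GSK126 replicate 3 the cholesterol median was 0.085 and the fatty acid median 0.07, and the cholesterol median was 0.12 without DMSO replicate 1 and 0.30 without GSK126 replicate 1. The G2/M median was −0.18 without DMSO replicate 2 and −0.46 without GSK126 replicate 2, the lysosome median 0.17 without GSK126 replicate 1, and the immediate early median −0.17 without GSK126 replicate 2.

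For a general list of developmental regulators known as Polycomb targets, no common direction was detected under GSK126. Whether EZH2 represses its members in these cells was not measured, so the list does not test that. Of 67 developmental regulators known as Polycomb targets, 40 were tested. The others had no kept probe with their symbol, so targets too dim to detect in these cells were not examined. The 40 tested had a median of 0.02 under GSK126 (camera adjusted p = 0.452). Of them 3 rose adjusted over the list alone (with the block 4 rose and 1 fell) and 0 over all genes by limma. TBX2 and SOX2 stood at 0.56 (SE 0.14) and 0.49 (SE 0.12). CDKN1C, also in this list, stood at 0.04 (limma adjusted p = 0.971). Outside the list, CDKN1A stood at 0.13 (0.836) and HDAC6 at 0.08 (0.828). PIK3IP1 stood at 0.35 (SE 0.20, limma adjusted p = 0.628), at 0.45, 0.60 and 0.00 in batches 1, 2 and 3. The PI3K-AKT inhibitor and FOXO list had a median of −0.03 and a mean of 0.02 over 30 members (camera adjusted p = 0.463), where TSC22D3 stood at 0.50 (SE 0.08, limma adjusted p = 0.157) and CDKN1B at −0.43 (SE 0.09, limma adjusted p = 0.268), and adjusted over the list alone 1 member rose and 1 fell. Cytokines and NF-kappaB targets had a median of −0.18 (camera adjusted p = 0.129), with PTGS2 at 0.72 (SE 0.20). Adjusted over that list alone 1 member fell, and with the block 1 rose and 1 fell.

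For the remaining lists under GSK126, camera gave an adjusted p of 0.463 for the PRC2 complex (median −0.08), 0.427 for SWI/SNF subunits (−0.02), 0.463 for p53 targets (0.07), 0.536 for apoptosis regulators (0.03), 0.176 for the unfolded protein response (−0.07) and 0.656 for the ATF4 response (0.04). It gave 0.0899 for oxidative phosphorylation (median 0.07), 0.0899 for ribosomal proteins (0.03), 0.546 for interferon-stimulated genes (−0.02), 0.164 for MHC antigen presentation (0.09) and 0.656 for epithelial junctions (−0.02). Mesenchymal genes had an adjusted p of 0.32 (median 0.11), basement membrane genes 0.91 (−0.05), clear cell markers 0.0899 (0.05), hypoxia and glycolysis 0.91 (−0.01), NRF2 genes 0.463 (−0.05), core histone genes 0.933 (median 0.03, with camera's direction downward) and leukocyte markers 0.895 (−0.08). Adjusted over the list alone with the block, 4 clear cell markers, 2 basement membrane genes and 1 p53 target rose. On the same count 2 mesenchymal genes fell, and without the block 0 members of these 4 lists passed. Among apoptosis regulators 1 rose adjusted over the list alone, with and without the block. FBLN1 stood at −0.16 (limma adjusted p = 0.687), and VWF was not above background in either group.

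The direct comparison of GSK126 with induced ARID1A asks where the interventions differ. Among the genes higher under GSK126 were PTGS2 at 2.31 (SE 0.20), CCL20 at 1.99 (SE 0.40) and SAA2 at 1.93 (SE 0.34). CD69 was at least 6.17-fold and LTB at least 3.72-fold higher, each above background on 1 of 3 arrays with induced ARID1A. Among the genes lower under GSK126, GALNT16, MYL4 and UPK2 were above background on 1 of 3 GSK126 arrays and at least 10.8-fold, 8.67-fold and 5.18-fold higher with ARID1A. ESPN and KRT13, not above background on any GSK126 array, were at least 5.79-fold and 4.64-fold higher with ARID1A. PIK3IP1 differed by −0.56 (SE 0.20, limma adjusted p = 0.19), so the difference between the interventions did not pass for this gene. Limma called 317 genes, 121 higher and 196 lower under GSK126, and 530 with batch as a block (230 higher and 300 lower). Leaving out 1 of the 6 arrays compared gave between 108 (without replicate 3 of the induced cells) and 170 (without replicate 2 of the induced cells). With median centring in place of quantile normalisation the split was 175 higher and 169 lower.

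Core histone genes (median −0.61, camera adjusted p = 6.15e-08), epithelial junctions and keratins (−0.08, 0.0025), basement membrane genes (−0.11, 0.0283) and lysosome genes (−0.06, 0.0409) had medians below 0 for GSK126 against induced ARID1A. With an estimated correlation these 4 lists did not pass (adjusted p = 0.271, 0.271, 0.366 and 0.456). Of 27 epithelial genes 5 were lower over all genes. Of 27 lysosome genes 0 passed over all genes, 1 was lower adjusted over the list alone (0 with the block), and 9 were positive. Cytokines and NF-kappaB targets (median 0.32, camera adjusted p = 1.8e-05), MHC antigen presentation (0.21, 0.00103), the ATF4 response (0.16, 0.0025), ribosomal proteins (0.04, 0.0191), cholesterol synthesis (0.13, 0.0283), fatty acid synthesis (0.24, 0.0341) and interferon-stimulated genes (0.16, 0.0409) had medians above 0. With an estimated correlation these 7 lists did not pass either (adjusted p = 0.271, 0.285, 0.271, 0.271, 0.532, 0.271 and 0.734, in this order). No interferon, ribosomal or cholesterol gene passed over all genes or adjusted over the list alone. Over all genes 1 ATF4 gene was higher, and 2 fatty acid genes were higher and 1 lower. Of the core histone genes 2 were lower over all genes (8 with batch as a block) and 12 adjusted over the list alone, and of the cytokine list 5 were higher and 1 lower on either count. With the block 4 basement membrane genes were lower (1 without it) and 3 MHC genes higher (0 without it, by limma). The medians in batches 1, 2 and 3 were −0.21, 0.62 and −0.03 for interferon-stimulated genes and −0.15, 0.10 and 0.55 for cholesterol synthesis. Without replicate 2 of the induced cells the interferon median was −0.08 (adjusted p = 0.806), and its call was also lost without GSK126 replicate 2 (median 0.09, 0.255) or 3 (0.04, 0.338), while the median was 0.325 without replicate 3 of the induced cells and 0.29 without GSK126 replicate 1. Without batch 3 the cholesterol median was −0.07, and without replicate 3 of the induced cells or of GSK126 its adjusted p was 0.305 (median 0.06) and 0.315, while the median was 0.21 without GSK126 replicate 1. Calls were lost too for fatty acid synthesis without replicate 3 of either group (0.111 for the induced cells, 0.0803 for GSK126) and for ribosomal proteins without replicate 3 of the induced cells (0.0662). The basement membrane call was lost without replicate 2 of either group (0.0724 and 0.113), and the lysosome call without replicate 2 (0.0724) or 3 (0.214) of the induced cells or GSK126 replicate 1 (0.222). The lysosome median was −0.12, −0.11 and −0.04 without replicates 1, 2 and 3 of the induced cells, and −0.10 and −0.11 without GSK126 replicates 2 and 3. Without replicate 2 of the induced cells the medians were 0.07 for MHC antigen presentation, 0.48 for cytokines, 0.06 for ribosomal proteins and −0.13 for epithelial junctions, which had −0.05 without GSK126 replicate 2. Without replicate 1 of the induced cells they were −0.175 for basement membrane genes and 0.06 for ribosomal proteins.

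Whether both interventions moved the same genes was asked from the calls and from the fold changes. As limma called 0 genes for GSK126 against DMSO (1185 at an unadjusted p below 0.05), the count called in both was 0. The 0 given by independent lists was fixed with it, so this count does not bear on the question. The genes called after ARID1A restoration had a median GSK126 value of 0.13 where they rose and −0.16 where they fell, against 0.81 and −0.64 with ARID1A. As these genes were chosen on the DMSO arrays that both comparisons share, values of the same sign are favoured, by an amount that was not computed. Across all genes, which are not independent replicates, the fold changes of the interventions had a Pearson correlation of 0.39, and 0.382, 0.428 and 0.35 within batches 1, 2 and 3. Without 1 array it lay between 0.318 (without GSK126 replicate 2) and 0.48 (without DMSO replicate 3), with 0.335 without GSK126 replicate 3 and 0.475 without DMSO replicate 2. Unchanged groups simulated against the same 3 controls with noise independent between genes gave a correlation of 0.501 on average (0.476 to 0.52), above the observed 0.39, and a covariance of 0.0141 (0.013 to 0.0151), below the observed 0.0224. With noise mixed from the measured residuals the correlation was 0.45 on average, over a range from −0.689 to 0.964, and the covariance 0.0132, from −0.013 to 0.0691. Neither simulation held a changed gene or a shared batch, while measured deviations of arrays from the same batch correlated by 0.102 to 0.326. Changes in only 1 intervention lower a correlation. An observed correlation below the simulated averages therefore does not bear on a shared response. As 3 controls cannot be split into parts of at least 2 arrays, part of any excess may come from the shared controls.

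**Figure D4:**
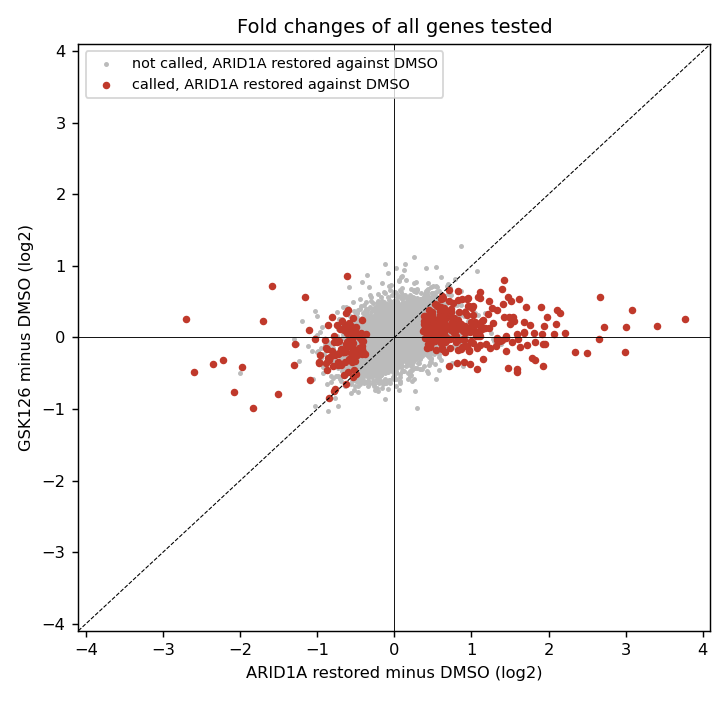
Log2 fold change against DMSO of each of 12698 genes with induced ARID1A (horizontal axis) and under GSK126 (vertical axis), with the 361 genes called after ARID1A restoration in red and equality as a dashed line. The median GSK126 value of the genes that rose with ARID1A is 0.13, against 0.81 with ARID1A.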

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

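The tests of mislabelled arrays, of a saturated probe, of a probe outside the induced transcript and of a wider spread under GSK126 were chosen after the results were seen; so was the simulation with noise independent between genes. Against the real counts of 361 and 317 genes for ARID1A against DMSO and GSK126 against ARID1A, the highest count of the other splits of the 6 arrays was 0 in each case, and 1 of 10 splits reached the real count. For GSK126 against DMSO the real count was 0, the highest other was 0, and 10 of 10 splits reached it. Of the 10 splits, 4 part all 3 batches like the real one, and the other 6 part 1 batch. The 10 splits are too few for a share under 0.05.

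The dimmer ARID1A probe, which the gene-level comparisons do not use, had a mean 2.981 higher with induced ARID1A than in DMSO, where it was not above background, so that only a rise of at least 3.74-fold is measured. The brighter probe differed by −0.129. Mislabelled induced arrays are argued against, since the dimmer probe was detected on 3 of 3 induced arrays and on 0 of the other 6, with a gap of 2.42 from the highest of the 6 to the lowest induced array, or of at least 1.53 against the dimmest signal above background. Saturation of the brighter probe is also argued against, because it lies 5.07 below the brightest value of the arrays. A brighter probe that lies outside the induced transcript, reading only the cell's own ARID1A messenger, stays open and cannot be told apart from other causes without probe and construct sequences, which were not used here.

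For the absence of calls for GSK126, a wider spread of its arrays is argued against by a ratio of 1.08 between the median SDs of GSK126 and DMSO. Changes of 1.5-fold too small for 3 arrays to call stay open. Of simulated ones 56.4% were called among larger changes, past the 50% set in advance to exclude this, but 46.6% when all changes were 1.5-fold. Both simulations changed 200 genes, used the spread moderated by eBayes and held no batch effect. Of simulated changes by a factor only 25% above 1, 0% were called, so many smaller changes may be present. The absence of any GSK126 effect stays open: the GSK126 changes covaried between batches by 0.0185, a value reached in 140 of 1000 simulated unchanged sets with noise mixed from the residuals and in 0 of 1000 with independent noise. The mixed noise is too alike between arrays and the independent noise ignores correlation between genes, so neither settles it.

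Fold changes of both interventions against DMSO went together, and shared DMSO arrays are the technical explanation. Taken between different batches, so that no array is shared, their covariance was 0.0146 and was positive in 6 of 6 pairs of batches. The 6 values lay between 0.0131 and 0.0173. The mean was reached in 142 of 1000 simulated unchanged sets with mixed noise and in 0 of 1000 with independent noise, where the highest value was 0.00152. These pairs share no array by construction, so shared DMSO arrays could not have been the source of this covariance, whatever its size. The covariance between batches therefore does not test that explanation. How far shared DMSO arrays account for the fold changes of all arrays going together stays open. Noise that is alike between arrays of different batches, as in the mixed noise, cannot be told apart from a shared response here. A biological overlap between ARID1A restoration and EZH2 inhibition remains open as well, as does an effect of doxycycline, which no group received alone among the samples analysed here.

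Signals also appeared in probes without a gene symbol, which no gene-level comparison uses: 56 were called for ARID1A against DMSO and 43 for GSK126 against ARID1A, with 0 for GSK126 against DMSO.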

How the results depend on the processing

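The 4 combinations of the block with a further choice were chosen after seeing the data. Genes called for ARID1A against DMSO, and for GSK126 against ARID1A, numbered 774 and 530 with the replicate block, 643 and 516 without background correction, 644 and 513 on the authors' table, 704 and 546 with a mean-variance trend, 232 and 168 with only the 2 groups compared, and 797 and 635 at an adjusted p threshold of 0.1. With the block they were 1453 and 1086 on the authors' table, 1471 and 1091 without background correction, 1583 and 1202 with the trend, and 781 and 638 with median centring. For GSK126 against DMSO the count of 0 held under each alternative fixed before the data were examined and under the block with median centring, and became 65, 69 and 129 under the block with the authors' table, without background correction and with the trend. Of these genes 31, 35 and 60 were also called for ARID1A in the same direction and 4, 4 and 8 in the opposite one; the DMSO arrays are shared and no value for unchanged groups was computed for these settings, so these counts do not bear on a shared response. Leaving out arrays of the groups compared lowered the counts. Without 1 array, ARID1A against DMSO gave 92 (DMSO replicate 1), 190 (DMSO replicate 2), 130 (DMSO replicate 3), 160, 218 and 92 (ARID1A replicates 1, 2 and 3), and up to 404 without GSK126 replicate 1. GSK126 against ARID1A gave 143, 170 and 108 without ARID1A replicates 1, 2 and 3, 114, 168 and 157 without GSK126 replicates 1, 2 and 3, and up to 255 without DMSO replicate 2. Without a batch the counts were 25 to 34 and 29 to 68, and with the block 57 to 72 and 40 to 59. ARID1A itself turned to 1.43 (1.426) under the mean of its probes, because that mean takes in the dimmer probe. Interferon-stimulated genes, GSK126 against ARID1A, turned to −0.077 without ARID1A replicate 2 and −0.0774 without batch 2, with or without the block, and reached 0.325 without ARID1A replicate 3. Cholesterol synthesis turned to −0.0665 without batch 3, and reached 0.295 without batch 1. The cause was not tested. Of 43 named genes called for ARID1A against DMSO, 35 stayed called in each alternative that keeps all arrays, and 7 in each that leaves out an array or batch; FEZ1 was at −0.16 (adjusted p = 0.665) under the stricter filter, and its range over those alternatives was 7.32e-05 to 0.665. PIK3IP1 had an adjusted p between 0.00224 and 0.0603 (without the filter) where all arrays are kept, and between 0.0255 and 0.191 where an array or batch is left out. Of the named genes not called, some stayed so in each alternative that keeps all arrays. These were 12 of 28 for ARID1A against DMSO, 47 of 63 for GSK126 against DMSO and 4 of 7 for GSK126 against ARID1A. For GSK126 against DMSO, TNFSF10, TSC22D3 and ECT2 each reached a limma adjusted p of 0.00677. They did so only under combinations with the block that were added after seeing the data. Of the 10 named genes called for GSK126 against ARID1A, 9 stayed called where all arrays are kept and 5 in each setting that leaves out an array or batch. Of 12, 6 and 11 lists called, 5, 3 and 5 stayed called in each of the latter. In each comparison 0 lists stayed called in every alternative that keeps all arrays, because these include the estimated correlation. For lists, and for genes named by the rule, the block changed no call other than those printed beside their results. Signal over background limits genes such as GALNT16 and TNF to bounds in 1 group. Of the 361 called genes, 35 were not above background on any array of 1 group. Genes detected on only some arrays of their dimmer group, such as MYL4, have bounds too and are not among the 35.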

Other observations

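The genes and families in this part were chosen after their values were seen. On the authors' value table with batch as a block, a combination added after 0 genes passed without it, 65 genes were called for GSK126 against DMSO, 41 higher and 24 lower, with a median size of 0.467. None of the 65 passed in the model without the block or with the block alone, where 0 genes were called by limma and 1185 and 1741 had an unadjusted p below 0.05. Among those higher were the death ligand TNFSF10 at 0.85 (SE 0.11, 1.81-fold), the retinal dehydrogenase ALDH1A1 at 0.81 (SE 0.11), the epidermal protein FLG at 0.77 (SE 0.09), and both PTGS2 at 0.69 (SE 0.11) and PLA2G4A at 0.67 (SE 0.08), which act in sequence in prostaglandin synthesis. Lower were the mitotic genes ECT2 at −0.47 (SE 0.07), KNTC1 at −0.54 (SE 0.10), PLK1 at −0.42 (SE 0.08) and TOP2A at −0.40 (SE 0.08), the repressor E2F7 at −0.53 (SE 0.10) and the DNA methyltransferase DNMT3B at −0.36 (SE 0.07). Under that setting PTGS2 and PLA2G4A stood at −1.44 and −0.42 with ARID1A.

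Genes were also grouped by the letters that start their symbol, in 420 families with at least 5 members. After ARID1A restoration the KRT family of keratins had a median of 0.38 over 11 members (camera adjusted p = 5.67e-06, and adjusted p = 0.955 with an estimated correlation), and KRT13, KRT8, KRT80 and KRT16P2 rose. The CXCL chemokines had a median of −0.55 over 7 members (camera adjusted p = 0.00848, and adjusted p = 0.955 with an estimated correlation), and CXCL1 and CXCL10 fell. GBP1 and GBP4, interferon-inducible GTPases, fell in a family of 5 with a median of −0.43 (camera adjusted p = 0.031, and adjusted p = 0.955 with an estimated correlation). The SNORD family of small nucleolar RNAs had a median of −0.14 over 57 members (camera adjusted p = 0.028, and adjusted p = 0.955 with an estimated correlation), and SNORD11 fell. Each of these 4 medians kept its sign without background correction, with median centring and on the authors' table, but without background correction they were 0.30 for KRT, −0.36 for CXCL, −0.17 for GBP and −0.07 for SNORD. For GSK126 against DMSO the smallest adjusted p of a family was 0.223.

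The first principal component held 34.7% of the variance and set the arrays with induced ARID1A, between 15.6 and 28.2, apart from the others, which lay at −6.06 or lower.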
